A study of Mus musculus with 16 samples.

How the data were processed

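RNA from MC38 cells, a mouse colon adenocarcinoma line, was profiled in 16 libraries. Per the labels, they comprised m6A immunoprecipitation libraries of WT cells (n = 3) and of Ythdf2-KO cells (n = 3), the matching input libraries (n = 3 each), YTHDF2 RNA immunoprecipitation (RIP) libraries (n = 2) and RIP inputs (n = 2). Sample titles tag the WT group gNC and the Ythdf2-KO group gY2, read here as guide names, so WT need not mean unmodified cells. Per the labels' protocols, m6A libraries were made from fragmented polyadenylated RNA pulled down with an antibody against N6-methyladenosine (m6A), a base modification of mRNA. YTHDF2 is a protein that binds m6A and recruits deadenylases. RIP libraries were made from cell lysate pulled down with an antibody against it.

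The authors deposited a table of whole-number read counts per gene for the 6 input libraries, with no normalization, and it held 0 columns of other samples. HISAT2, HOMER, ChIPseeker and the genome build mm10 are named in the submitters' processing notes, with no role given to each. The counter, its strand setting, the annotation release and the peak caller are not given in the sources used here. The authors also deposited 3 peak lists, 1 each for WT m6A, Ythdf2-KO m6A and YTHDF2 RIP, in which each peak is a set of exonic blocks assigned to a gene and carries a value that the file headers call only a score. All of these deposited scores lay between 0 and 0.003, so they were read as p-values, from the values alone. Each group has 1 list, and how its libraries were combined is not given in the sources used here, so peaks carry no replicate error, and intervals on shares of peaks are exact Clopper-Pearson intervals (95%) for counting error only. IP and RIP signal per library was not analysed here.

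The count table held 55401 genes, each with a symbol. Of these, 55141 were found in GENCODE release M21 (GRCm38, the assembly of mm10), from which gene positions, transcripts and sequences were taken. Where a symbol in a gene list had several rows, the row with most counts was used. Total counts per library ran from 45441281 to 50959555. At these depths 3 counts correspond to 0.059 to 0.066 CPM, the level that a count of 0 still allows, for counting error only. The most abundant gene took 1.43% to 2.10% of counts. No library pair agreed within sampling noise: the chi-square per degree of freedom was 9.07 for the closest pair. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

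Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (TMM factors, filterByExpr, no covariate, Benjamini-Hochberg adjustment at 0.05) in R 4.3.3, over 18969 genes. The standard error given with a log2 fold change is its size divided by the square root of F. Values in CPM use TMM-scaled library sizes, and ± is the SD over n = 3 libraries. Fold changes are Ythdf2-KO over WT. On simulated counts with the means, dispersions and library sizes of these 18969 genes, 200 genes were changed. Genes of the lowest abundance were left out of that draw. Noise was drawn for each gene alone, so a shift of many genes in a single library was not simulated. The test recovered 74.0% of 2-fold changes and 95.0% of 4-fold changes. It made 187 calls, of which 9.6% were on unchanged genes. In a separate simulation in which no gene was changed it made 0 calls.

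Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over 18 lists. The lists covered chemokines, type I interferon-stimulated genes, class I antigen presentation, checkpoint and immunoregulatory molecules, NF-kB targets, immediate early genes, cell cycle, p53 targets, the integrated stress and unfolded protein responses, and epithelial to mesenchymal transition with extracellular matrix. They also covered glycolysis, oxidative phosphorylation, m6A factors, mRNA decay, lysosome and autophagy, cholesterol synthesis, leukocyte and endothelial markers, and fibroblast markers. Each list's median was placed among 10000 random lists matched on mean expression in 20 bins.

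Peaks were compared with bedtools 2.31.1, counting an overlap of at least 1 exonic base on the same strand. Each peak centre was placed on the coding transcript with the longest coding sequence of its gene, and shares were set beside those of centres spread evenly over the same transcripts. RIP peaks in m6A-marked genes were also placed at random within their transcripts 100 times. The DRACH consensus of m6A was counted per kilobase in peaks and in unpeaked parts of the same transcripts, with the reversed motif as a control. A gene was called bound where it had a RIP peak and marked where it had a WT m6A peak. The 6 sets made from these classes were tested with camera as above.

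Tests, groups, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Ythdf2, the 12 largest rises and 12 largest falls, and up to 4 members per list. The largest changes were taken among genes past the threshold, at 5 CPM or more in the higher group, with no overlap between groups and without unnamed models. It also took 8 top peaks per peak list, the peaks of Ythdf2, Cx3cl1, Myc, Actb and Gapdh, and 15 bound and marked genes with the smallest p. Cx3cl1 was included because the study is known to be about it, so it is not independent of these samples. The genes B2m, Cxcl1, Cxcl10, Cd274, Vim, Nfkbia, Lif, Tnfaip3, Col1a2 and Col6a1, which did not pass, were named after their values were seen. So was Ifi47, for its overlap with Olfr56. One gene that the rule named is not reported here. Peaks tied at a score of 0 were ordered by width, a choice made after the data were seen. Alternatives were DESeq2 1.42.0, its size factors within edgeR, other count filters, a fold threshold, the replicate number as a block, each library left out, fry and estimated correlations, and other overlap rules.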

Results

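The series compared MC38 colon tumour cells labelled WT with MC38 cells labelled Ythdf2-KO, and mapped m6A and YTHDF2-bound sites on their transcripts. Gene counts covered the 3 WT and 3 Ythdf2-KO input libraries. Their total counts were 45441281, 46452917 and 50885512 in WT and 50241259, 50959555 and 48736352 in Ythdf2-KO. Peak lists covered WT m6A (19236 peaks in 9427 genes), Ythdf2-KO m6A (17428 peaks in 8686 genes) and YTHDF2 RIP (23372 peaks in 6754 genes).

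The first comparison asked which transcripts differ when Ythdf2 is knocked out. Ythdf2 itself (ENSMUSG00000040025.17, mm10 chromosome 4, 132184912 to 132212303, minus strand) did not differ in whole-gene reads. Its level was 55.6, 68.6 and 59.7 CPM in the WT libraries and 67.9, 59.8 and 61.5 CPM in the Ythdf2-KO libraries (log2 fold change 0.04, SE 0.10, edgeR adjusted p = 0.809). A whole-gene count includes exons outside an edited site, so it does not check the knockout. The libraries are therefore called KO-labelled, and each direction below rests on the labels. Cx3cl1 (ENSMUSG00000031778.13, chromosome 8, 94772009 to 94782427, plus strand), which encodes the chemokine fractalkine, was higher in the KO-labelled libraries. It measured 7.04 ± 0.880 CPM in WT and 19.5 ± 6.03 CPM in KO-labelled cells (SD, n = 3), a log2 fold change of 1.47 (SE 0.25, edgeR adjusted p = 0.0336). The KO-labelled replicates stood at 12.6, 22.8 and 23.2 CPM. With single libraries left out its edgeR adjusted p ran from 0.000155, without KO-labelled replicate 1, to 0.176, without WT replicate 3, and it was below 0.05 in 1 of the 6 fits. Cx3cl1 was named because the study is about it, so its rise is not independent of these samples.

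**Figure D1:**
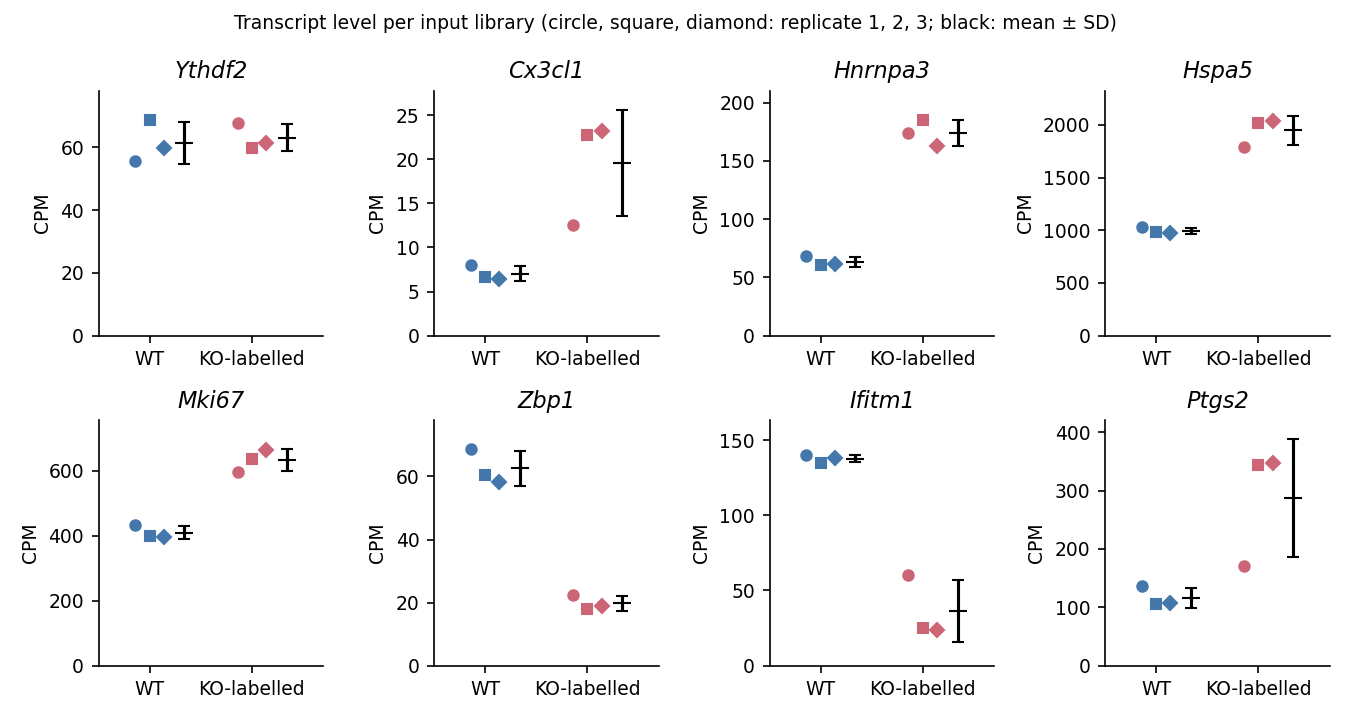
Transcript level in CPM (y axis, from 0) of 8 genes in each of the 3 WT and 3 KO-labelled input libraries, one marker per replicate number, with the mean and SD in black. Ythdf2 overlaps between groups, Hnrnpa3 and Zbp1 are separated in all 3 KO-labelled libraries, and KO-labelled replicate 1 lies nearer to WT than to replicates 2 and 3 for Cx3cl1 and Ptgs2, but not for Ifitm1.

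Over 18969 genes, 568 were higher and 293 lower in the KO-labelled libraries at an edgeR adjusted p below 0.05. Of these, 148 rose and 135 fell by at least 2-fold. All 861 had no overlap between the WT and KO-labelled values. That held for 33.8% of all tested genes, where chance gives 10%. Most called genes were protein-coding (550 of the higher, 222 of the lower). KO-labelled replicate 1 stood between the groups. On the first principal component (51.4% of variance) the WT libraries lay at -39.1, -38.6 and -39.2, KO-labelled replicate 1 at -10.4, and replicates 2 and 3 at 64.1 and 63.2. WT replicate 1 also stood apart from its group: the chi-square per degree of freedom was 30.7 and 28.4 against the other WT libraries, 30.1 against KO-labelled replicate 1 and 9.07 between WT replicates 2 and 3. On the second component (15.5%) WT replicate 1 (9.7) and KO-labelled replicate 1 (50.5) were above 0 and the other 4 libraries below. With KO-labelled replicate 1 left out, edgeR called 3782 genes higher and 3144 lower, among them all 861. Leaving out any other library left 0 to 53 higher and 0 to 40 lower: 53 and 40 without WT replicate 1, 0 and 0 without WT replicate 2, 3 and 2 without WT replicate 3, 1 and 3 without KO-labelled replicate 2, and 1 and 0 without KO-labelled replicate 3. At an unadjusted p below 0.05, edgeR counted 5596 genes with all libraries, 4011 without WT replicate 2 and 3457 without KO-labelled replicate 3. DESeq2 on all 6 libraries called 2244 higher and 1346 lower.

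Among the largest rises, the matrix protease gene Mmp3 (stromelysin) went from 0.468 ± 0.236 to 15.1 ± 9.68 CPM (log2 fold change 5.00, SE 0.72), and the endothelial adhesion molecule Sele from 0.528 ± 0.256 to 13.1 ± 5.88 CPM (4.64, SE 0.53). They were followed by Mmp9 (3.57), S100a8 (3.47), Mmp13 (3.23), Adamts7 (2.85), the peptide hormone Cck (2.84), Rgs16 (2.73), Calcrl (2.22), Plat (2.21), Fam131b (2.06) and Rhpn1 (2.04). The spread among KO-labelled libraries was wide for these genes. Mmp3 measured 3.98 CPM in replicate 1 and 21.4 CPM in replicate 3, and S100a8, which encodes a calcium-binding protein of myeloid cells, was at 7.32 CPM in replicate 1 and 30.3 CPM in replicate 2. The largest falls were in Myh14 (-2.63), Stra6 (-2.51), Tenm4 (-2.50), the interferon-induced GTPase Tgtp1 (-2.42), Cd48 (-2.12), the lipid droplet protein Plin4 (-2.07), Atg9b (-2.04), Olfr56 (-1.99), Cdsn (-1.96), the long noncoding RNA Platr3 (-1.94), Ifitm1 (-1.92) and Rgcc (-1.90). Ifitm1, an interferon-induced antiviral membrane protein, measured 138 ± 2.59 CPM in WT and 36.2 ± 20.6 CPM in KO-labelled cells. Without KO-labelled replicate 1 the falls of 4 genes were over 1.5 times as large on the linear scale: Tgtp1 (-3.40), Stra6 (-3.37), Myh14 (-3.24) and Plin4 (-2.88). So was the rise of Mmp9 without WT replicate 1 (4.16). The edgeR adjusted p of these 24 genes ran from 0.0124 to 0.0497. Of the 24, 10 overlap an annotated gene on the other strand, and Tgtp1 and Olfr56 overlap each other, so their values are uncertain where counting ignored strand. Stra6, Tenm4, Tgtp1, Cd48 and Olfr56 also overlap an annotated gene on their own strand, so reads may be shared with strand counted too. For Olfr56 that gene is Ifi47, at 10.9 CPM in WT and 2.56 CPM over KO-labelled replicates 2 and 3, so the fall of Olfr56 may be that of Ifi47. Tgtp1 also has a close paralog, Tgtp2. With single libraries left out, 4 of the 24 kept their call in 2 or more of the 6 fits.

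Of 41 type I interferon-stimulated genes tested, 8 fell in the KO-labelled libraries, 1 rose and 32 did not pass (29 fell and 1 rose when adjusted over the list alone), and the median log2 fold change was -0.53. Zbp1, a sensor of Z-form nucleic acids, fell from 62.5 ± 5.55 to 19.7 ± 2.24 CPM (-1.66, SE 0.11), and its KO-labelled replicate 1, at 22.3 CPM, was close to replicate 3, at 18.9 CPM. The deconjugase Usp18 fell by 0.65 and the transcription factor Irf7 by 0.72 on the log2 scale, while Ifit2 rose from 36.5 ± 0.607 to 54.2 ± 3.01 CPM. The camera adjusted p was 1.02e-09 with the preset correlation. With an estimated correlation the adjusted p = 0.599. When KO-labelled replicate 1 was left out, 33 members were lower and 1 was higher.

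Among genes of class I antigen presentation, 7 of 25 fell, 1 rose and 17 did not pass (9 fell and 2 rose when adjusted over the list alone). The peptide transporter subunit Tap2 fell from 87.7 ± 3.39 to 55.3 ± 4.56 CPM, the trimming peptidase Erap1 by 0.75 and the proteasome activator Psme2 by 0.42 on the log2 scale. The chaperone Calr, which also acts outside this pathway, rose from 1040 ± 49.6 to 1620 ± 191 CPM. The light chain B2m measured 805 ± 19.8 and 792 ± 121 CPM and did not pass. The list's camera adjusted p was 0.0309, and with an estimated correlation the adjusted p = 0.599. Leaving out KO-labelled replicate 1 gave 9 members lower and 6 higher, and the camera adjusted p was 0.533.

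Of 15 chemokine genes tested, Cx3cl1 rose, Ccl8 fell (from 18 ± 2.51 to 10.7 ± 1.26 CPM) and 13 did not pass (4 rose and 1 fell when adjusted over the list alone). The list's median log2 fold change was 1.13, with a camera adjusted p of 0.144. Cxcl1, a neutrophil attractant, measured 30.3 ± 4.88 CPM in WT and 262 ± 210 CPM in KO-labelled cells. Cxcl10, which attracts T cells, measured 60.1 ± 14.4 and 152 ± 76.3 CPM, and neither passed (edgeR adjusted p = 0.081 and 0.0856). In KO-labelled replicate 1 Cxcl1 stood at 19.8 CPM and Cxcl10 at 64.3 CPM. Their means over replicates 2 and 3 were 383 and 196 CPM, so the higher KO-labelled means rest on those libraries. In the fit without KO-labelled replicate 1, 10 chemokine genes were higher and 2 lower, with a camera adjusted p of 0.000141 (0.186 with an estimated correlation). The study singled out Cx3cl1, so the list's direction is not wholly independent evidence.

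Of 23 NF-kB targets, 1 rose: Ptgs2, which encodes cyclooxygenase-2, from 116 ± 17.0 to 287 ± 101 CPM. Its KO-labelled replicates stood at 171, 343 and 348 CPM. When adjusted over the list alone, 11 rose and none fell. The list's median was 0.44, with a camera adjusted p of 4.11e-05 and, with an estimated correlation, an adjusted p = 0.599. The fit without KO-labelled replicate 1 gave 21 of the 23 higher. Nfkbia averaged 37.6 CPM in WT, stood at 35.9 CPM in KO-labelled replicate 1 and averaged 133 CPM over replicates 2 and 3. Lif stood likewise at 9.27, 10.5 and 38.4 CPM, and Tnfaip3 at 5.6, 6.86 and 21.7 CPM. For these genes the higher KO-labelled means rest on replicates 2 and 3, unlike for Ptgs2, already at 171 CPM in replicate 1. Of 30 immediate early genes, 2 rose and 1 fell, also when adjusted over the list alone, with a median of 0.34. The phosphatase gene Dusp2 rose from 3.63 ± 0.511 to 8.13 ± 0.769 CPM and the antiproliferative gene Btg2 from 3.51 ± 0.241 to 7.04 ± 1.64 CPM. The transcription factor Klf4 fell from 78.7 ± 1.69 to 46.7 ± 7.86 CPM. That list's camera adjusted p was 0.0309, and with an estimated correlation the adjusted p = 0.599. Leaving out KO-labelled replicate 1 gave 12 immediate early genes higher and 1 lower.

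Of 14 checkpoint and immunoregulatory genes, 1 rose, 2 fell and 11 did not pass (5 rose and 2 fell when adjusted over the list alone), with a median of 0.21 and a camera adjusted p of 0.400. The direction of fry for this list was down, against the sign of its median. Raet1e, which encodes a ligand of the NKG2D receptor, measured 23.2 ± 1.20 CPM in WT and 40.5 ± 6.81 CPM in KO-labelled cells, though its gene model overlaps Raet1d and H60b, so reads may be shared. Vsir fell from 6.30 ± 0.129 to 3.71 ± 0.115 CPM and Tnfrsf14 by 1.25 on the log2 scale. Cd274, which encodes PD-L1, measured 6.04 ± 0.913 and 5.38 ± 0.746 CPM and did not pass. When KO-labelled replicate 1 was left out, 7 members were higher and 2 lower.

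Of 36 cell cycle genes, 9 rose, none fell and 27 did not pass (28 rose when adjusted over the list alone), with a median of 0.41. The proliferation marker Mki67 went from 410 ± 20.8 to 633 ± 34 CPM, the cyclin genes Ccne1 from 19.7 ± 0.550 to 34.5 ± 3.66 CPM and Ccnd1 from 125 ± 6.72 to 190 ± 12.9 CPM, and the transcription factor E2f1 from 58.5 ± 0.912 to 105 ± 15.4 CPM. The camera adjusted p was 1.02e-09, and with an estimated correlation the adjusted p = 0.599. With KO-labelled replicate 1 left out, 30 were higher and 1 lower. Of 20 p53 targets, 4 rose, none fell and 16 did not pass (7 rose and 4 fell when adjusted over the list alone, and by DESeq2), with a median of 0.05 and a camera adjusted p of 0.400. The rises were in the stress cytokine gene Gdf15 (23.4 ± 8.39 to 86.3 ± 30.6 CPM), Phlda3 (0.60), the death receptor gene Tnfrsf10b (0.50) and Gtse1 (0.61). In the fit without KO-labelled replicate 1, 9 p53 targets were higher and 5 lower.

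Of 28 genes of the integrated stress and unfolded protein responses, 6 rose, 1 fell and 21 did not pass, also when adjusted over the list alone. The endoplasmic reticulum chaperone Hspa5 went from 997 ± 27.6 to 1950 ± 140 CPM (log2 fold change 0.97, SE 0.07), and its KO-labelled replicates all stood at or above 1790 CPM. Sdf2l1 rose by 1.32, the disulfide isomerase Pdia4 by 0.76 and the serine synthesis enzyme Psat1 by 0.55 on the log2 scale. The list's camera adjusted p was 0.0309, and with an estimated correlation the adjusted p = 0.599. Leaving out KO-labelled replicate 1 gave 8 members higher and 4 lower, and the camera adjusted p was 0.239.

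In the list of epithelial to mesenchymal transition and extracellular matrix, 5 of 36 rose, none fell and 31 did not pass (16 rose and 4 fell when adjusted over the list alone, 14 and 3 by DESeq2), with a median of 0.27. Mmp3, Mmp9, Mmp13 and Mmp10, which are secreted matrix proteases, were among them. Mmp10 had no read in any WT library and 2.72 ± 1.72 CPM in KO-labelled cells, at least 43.0-fold higher against 3 counts per WT library. The mesenchymal filament gene Vim measured 2280 ± 303 and 1810 ± 64.2 CPM and did not pass. Nor did the collagen genes Col1a2, at 50.5 CPM in WT, 25.8 in KO-labelled replicate 1 and 2.4 over replicates 2 and 3, and Col6a1, at 842, 642 and 262. Col1a2 is also in the fibroblast list. Fold changes were above 0 for 25 members and below 0 for 11. Epithelial and mesenchymal genes are mixed in this list, so its direction does not show a transition. The camera adjusted p was 0.0309, and with an estimated correlation the adjusted p = 0.599. When KO-labelled replicate 1 was left out, 18 were higher and 9 lower, with a camera adjusted p of 0.0573. With all libraries and the replicate block, the list's camera adjusted p was 0.0556. As markers of other cell types, 6 of 21 leukocyte and endothelial genes and 9 of 11 fibroblast genes passed the expression filter. Of the 6, the T cell receptor component Cd3d fell from 1.11 ± 0.145 to 0.383 ± 0.141 CPM and 5 did not pass. Of the 9, the matrix proteoglycan gene Dcn fell from 58.5 ± 8.82 to 33.2 ± 4.77 CPM and 8 did not pass. Adjusted over each list alone, 2 leukocyte or endothelial markers and 1 fibroblast marker fell. The camera adjusted p was 0.126 and 0.0730 for these lists, and 0.599 for both with an estimated correlation. The fibroblast list passed without KO-labelled replicate 1 (camera adjusted p 0.0114), without WT replicate 3 (0.0123) and with the replicate block (0.0195), and the leukocyte and endothelial list with fry (0.0296). With KO-labelled replicate 1 left out, 3 leukocyte or endothelial markers were lower and 2 higher, and 7 fibroblast markers were lower and 1 higher.

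**Figure D2:**
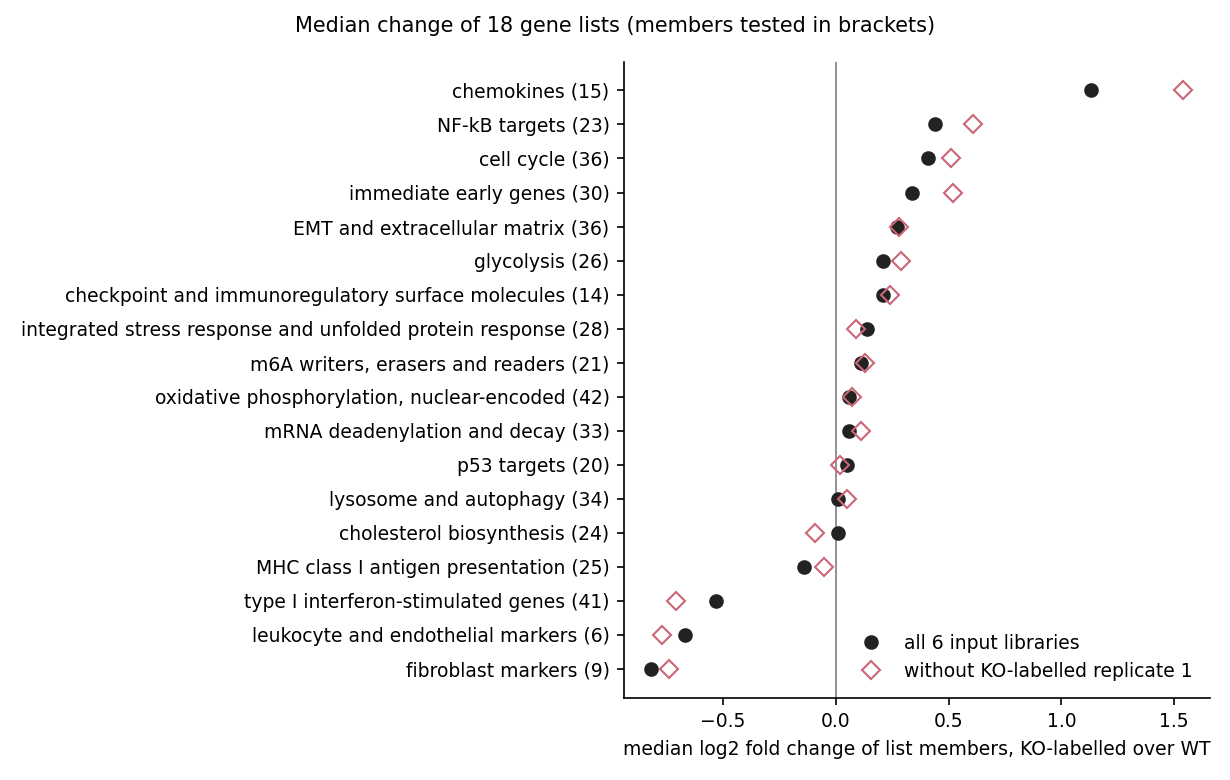
Median log2 fold change (x axis, KO-labelled over WT) of the members of 18 gene lists (y axis, members tested in brackets), with all 6 input libraries (filled circles) and without KO-labelled replicate 1 (open diamonds). Chemokines (1.13), NF-kB targets (0.44) and cell cycle genes (0.41) lie highest, and fibroblast markers (-0.82) and interferon-stimulated genes (-0.53) are among the lowest.

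The second comparison asked whether m6A sites differ between the genotypes. Of 19236 WT m6A peaks, 80.3% (95% exact interval 79.8 to 80.9) were overlapped by a KO-labelled peak, and of 17428 KO-labelled peaks 89.3% (88.9 to 89.8) were overlapped by a WT peak. Of marked genes, 8306 were listed in both, 1121 for WT alone and 380 for KO-labelled cells alone. Peak centres lay alike along the transcript in the 2 lists. In WT, 4.02% lay in the 5′ UTR, 61.1% in the coding sequence and 34.9% in the 3′ UTR, and in KO-labelled cells 3.92%, 62.2% and 33.9%. Centres within 200 bases of the stop codon made up 25.8% (25.2 to 26.5) in WT and 25.7% (24.97 to 26.38) in KO-labelled cells, where an even spread gives 12.5%. The DRACH motif was 1.28 times (95% bootstrap interval 1.26 to 1.29) as dense in WT peaks as in unpeaked parts of the same transcripts, against 1.15 for the reversed motif. The depth of the IP libraries is unknown here, so the difference in peak number has no test.

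In the WT list 421 m6A peaks were tied at a deposited score of 0, and in the KO-labelled list 390. With unnamed gene models left out and 1 peak per gene, the 8 widest of these in WT lay in Ahnak, Map1b, Phf3, Eif3a, Rrbp1, Tnks1bp1, Ppig and Cald1, with their centres in coding sequence. Chosen likewise, the 8 widest in the KO-labelled list lay in 6 of these genes and in Mki67 and Ankrd11. The Ahnak peak spanned 2789 bases (chromosome 19, 9009323 to 9012111). Cx3cl1 carried 1 m6A peak in its coding sequence in each list, at chromosome 8, 94779608 to 94779938 in WT and 94779698 to 94779818 in KO-labelled cells. Ythdf2 also carried 1 in each, of 1734 and 1764 exonic bases. Myc had 4 peaks in WT and 3 in KO-labelled cells, the longest near its stop codon (chromosome 15, 61989419 to 61990165 in WT). Actb had 2 in each list in its 3′ UTR, and Gapdh had 1 in the KO-labelled list (chromosome 6, 125161835 to 125161925).

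**Figure D3:**
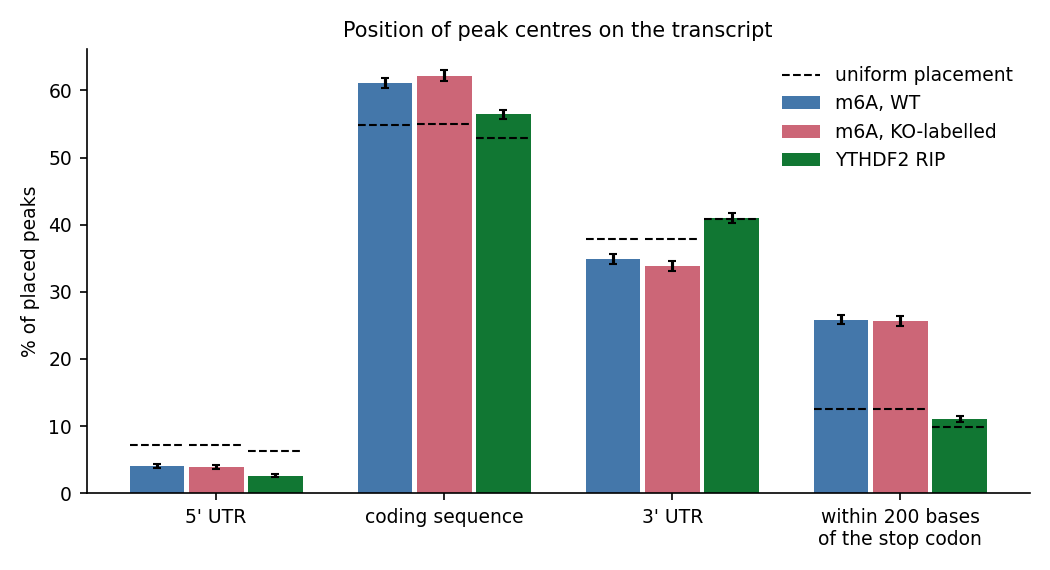
Percentage of placed peaks (y axis) whose centre lies in the 5′ UTR, coding sequence or 3′ UTR, or within 200 bases of the stop codon, for the WT m6A, KO-labelled m6A and YTHDF2 RIP lists, with 95% exact intervals for counting error. Dashed lines give an even spread over the same transcripts; near the stop codon the m6A lists reach 25.8% and 25.7% and the RIP list 11.1%.

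The third comparison asked how far transcripts bound by YTHDF2 carry m6A. Of 23372 RIP peaks, 34.2% (33.6 to 34.8) overlapped a WT m6A peak, and 48.3% of WT m6A peaks overlapped a RIP peak. Among RIP peaks in marked genes that could be placed at random within their transcripts (13022), 36.3% (35.4 to 37.1) overlapped an m6A peak, against 30.5% to 32.0% over 100 random placements. RIP centres near the stop codon made up 11.1% (10.7 to 11.5), against 9.80% for an even spread. The DRACH motif was 1.08 times (1.06 to 1.09) as dense in RIP peaks as outside them, and the reversed motif 1.10 times (1.088 to 1.116). By gene the overlap was larger. Of 6503 bound genes among those tested, 85.3% were marked, against 29.7% of unbound genes. The odds ratio was 13.7 (12.7 to 14.9, Fisher's exact test), and 7.07 (6.47 to 7.73) when stratified by expression quintile. Genes are not replicates, so these ratios describe the lists.

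The leading RIP peaks lay in Rnf213, Ahnak, the matrix gene Fn1, Sp3, Polr1d, Tsc22d1, the methionine adenosyltransferase gene Mat2a and Tiparp. The Mat2a peak, 629 bases wide (chromosome 6, 72433905 to 72434533), had its centre in the 3′ UTR, 77 bases past the stop codon. The Fn1, Polr1d and Mat2a peaks did not overlap a WT m6A peak, and the other leading peaks did. Cx3cl1 had 3 RIP peaks, of which the one at chromosome 8, 94779728 to 94779848 overlapped its m6A peak. That peak had a deposited score of 0.00012 and the others 1.2e-07 and 5e-05. All were weaker than the median score of the RIP list (1.9e-08). Myc had 2 RIP peaks and Ythdf2 had 1, all overlapping m6A peaks.

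The fourth comparison asked whether transcripts that are bound and marked are higher in KO-labelled cells. The 5544 genes of this class had a median log2 fold change of 0.09 (95% bootstrap interval over genes 0.08 to 0.10), with 295 called higher and 82 lower. Marked but unbound genes (3697) had a median of 0.01 with 125 higher and 70 lower, bound but unmarked genes (959) a median of 0.00 with 28 and 23, and genes with neither (8769) a median of -0.11 with 120 and 118. The share of higher genes among the called ones was 78.2% in the bound and marked class and 50.4% among genes with neither (odds ratio 3.53, 2.45 to 5.11, Fisher's exact test). Stratified by expression quintile, an alternative added after the data were seen, that odds ratio was 1.81 (1.16 to 2.81, exact conditional test). In the second quintile, 8 bound and marked genes were higher and 15 lower, against 38 and 49 with neither. The share was 64.1% in the marked but unbound class (odds ratio 2.01, 1.35 to 3, and 2.09, 1.36 to 3.22, when stratified). None of 10000 random lists matched on expression had a median as high as the bound and marked genes, and the highest was 0.06. These lists treat genes as independent and were not matched on transcript length. The marked but unbound class lay below its matched lists, whose median was 0.03, with all 10000 at or above it. The camera adjusted p of the bound and marked set was 0.000104 with the preset correlation, and with an estimated correlation the adjusted p = 0.0415. All bound genes and all marked genes were also up by camera, and genes with neither were down. Each of these sets had a camera adjusted p of 0.000117, and 0.0415 with an estimated correlation. With the preset correlation it was 0.651 for marked but unbound genes and 0.972 for bound but unmarked genes. When KO-labelled replicate 1 was left out, 1829 bound and marked genes were higher and 938 lower, against 856 and 1259 with neither. The bound and marked median was then 0.10, with a camera adjusted p of 0.152 with an estimated correlation. With splines of expression, transcript length and GC content in a linear model, an alternative added after the data were seen, the class lay at -0.022 (-0.050 to 0.002) from genes with neither.

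Bound and marked genes with the smallest p among the rises were led by Hnrnpa3 (ENSMUSG00000059005.13, chromosome 2, 75659261 to 75669407), which encodes a nuclear RNA-binding protein. It went from 63.4 ± 4.36 to 174 ± 10.7 CPM (log2 fold change 1.46, SE 0.08, edgeR adjusted p = 0.00548), with KO-labelled replicate 1 at 174 CPM, and was called in 5 of the 6 fits that left out a library. It was followed by Hspa5, the growth factor gene Gdf11 (1.41), the transcriptional regulator Id1 (0.99), Chpf (0.89), the choline transporter gene Slc44a1 (0.71), Creld2 (0.74), Phlda1 (1.79), the acid sphingomyelinase gene Smpd1 (0.69) and Hspa13 (0.72). The falls were led by the phosphodiesterase gene Pde4b (-1.37), Abca8b (-1.31), the matrix glycoprotein gene Thbs1 (136 ± 11.9 to 54.5 ± 11.1 CPM), Hspa12a (-1.31) and Tap2. Cx3cl1 also belonged to this class.

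**Figure D4:**
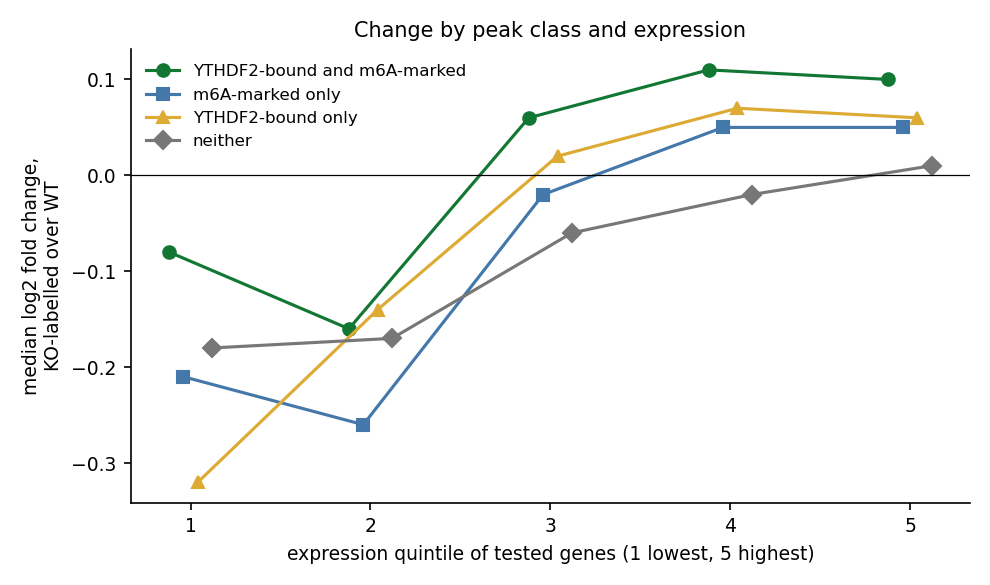
Median log2 fold change (y axis, KO-labelled over WT) of 4 classes of genes by expression quintile (x axis, 1 lowest), with classes set by the YTHDF2 RIP and WT m6A peak lists. In the fourth quintile the bound and marked class lies at 0.11 and genes with neither at -0.02; in quintiles 1 and 2 all 4 classes lie below 0.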

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

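The offset, the estimated correlation of the bound set, the odds ratios stratified by expression and the share of KO-labelled peaks were chosen after seeing the data. Against 568 genes higher and 293 lower, DESeq2 called 2244 and 1346, a filter of at least 1 count 70 and 41, a filter of 50 counts in 3 libraries 800 and 449, and a 2-fold threshold 148 and 135. Deviations of same-numbered libraries from their group means correlated at r = 0.05, 0.11 and 0.05, not all over 0.1, so the samples were not treated as paired, though each of the 6 correlated best with its own number; with the replicate number as a block 45 and 26 were called, and 63 of these 71 were among the 861. Leaving out one library gave 0 to 3782 higher and 0 to 3144 lower, the most without KO-labelled replicate 1; fewer libraries and, with that replicate kept, its distance from replicates 2 and 3 accompany the low counts, and the cause was not tested. Of 75 named genes, 72 had a call; all 72 lost it without WT replicate 2, 20 of the 75 stayed as they were with the replicate block, and no called gene turned direction. Of 18 lists, 8 passed with the preset correlation, 0 with an estimated one (lowest unadjusted p 0.086), 2 with fry and 5 to 8 without one library (5 without WT replicate 1). The bound and marked median kept its sign and call in 12 alternatives (0.07 to 0.10), lost its call with an estimated correlation and KO-labelled replicate 1 left out (adjusted p = 0.152), and lay at -0.022 as an offset beside splines of expression, length and GC content. Shared WT m6A peaks moved from 80.3% to 74.95% with 50% coverage, 85.2% in the higher-scoring 50%, 81.3% of merged exonic blocks and 89.3% of KO-labelled peaks. RIP peaks overlapping m6A moved from 34.2% to 18.2% with 50% coverage, 31.7% in the higher-scoring 50% and 31.4% with the KO-labelled list. The cause of these moves was not tested.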

Other observations

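The tests of a swap, of transcript level at WT-only peaks, of slopes on other peak counts and of other splits were chosen after the results were seen. Of 26 glycolysis genes, the neuronal enolase gene Eno2 rose from 34.5 ± 3.14 to 53.4 ± 8.48 CPM and 25 did not pass. None passed when adjusted over the list alone with edgeR, 10 had an unadjusted p below 0.05, and DESeq2 called 6 higher and 1 lower. The median was 0.21, with a camera adjusted p of 0.0309 and, with an estimated correlation, an adjusted p = 0.599. With KO-labelled replicate 1 left out, 13 were higher and 2 lower. None of 42 oxidative phosphorylation genes passed with edgeR, also when adjusted over the list alone (12 at an unadjusted p below 0.05; DESeq2 9 higher and 1 lower; camera adjusted p 0.144). Sdhc had the smallest edgeR adjusted p (0.0532). Without KO-labelled replicate 1, 9 were higher and 1 lower.

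None of 21 m6A writers, erasers and readers passed with edgeR, also when adjusted over the list alone (6 at an unadjusted p below 0.05; DESeq2 3 higher and 1 lower; camera adjusted p 0.337). The demethylase gene Fto measured 82.5 ± 1.40 and 98.5 ± 8.16 CPM (edgeR adjusted p = 0.0905). Of 33 deadenylation and decay genes Btg2 alone rose, also when adjusted over the list alone, with a camera adjusted p of 0.163. Of 34 lysosome and autophagy genes Atg7 fell (42.6 ± 5.30 to 29.6 ± 0.389 CPM), 2 rose and 2 fell when adjusted over the list alone, and the camera adjusted p was 0.881. The list of 24 cholesterol synthesis genes had a camera adjusted p of 0.363. Without KO-labelled replicate 1, 5 m6A factors, 5 decay genes, 9 lysosome genes and 5 cholesterol genes were higher, and 3, 1, 6 and 6 were lower.

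KO-labelled replicate 1 lay between WT and the other KO-labelled libraries: over 716 genes called without it, changed at least 2-fold, its median position from WT (0) to the mean of replicates 2 and 3 (1) was 0.27. A mixture of WT and KO RNA at 1 share predicts the same position for all genes. Rising genes lay at 0.19 (0.16 to 0.21) and falling genes at 0.40 (0.36 to 0.43), a gap of 0.22 before rounding that argues against such a mixture alone. A mixture joined by another difference, such as the one shared with WT replicate 1 on the second component, was not tested. A swap with a WT library of this set needs a WT library near replicates 2 and 3. The highest such correlation was 0.968, below the lowest between WT libraries (0.984). KO-labelled replicate 1 correlated at 0.981 to 0.982 with the WT libraries and at 0.973 to 0.975 with replicates 2 and 3, so it lay nearer to WT. A label error without an exchange in this set was not tested. A different clone, passage or culture stays open, and no biological explanation was tested.

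Bound and marked genes lay above the other genes in KO-labelled cells, by 0.16 in median against genes with neither at over 1 CPM, and are longer (median transcript 4153 against 1552 bases) and more abundant (42.2 against 7.03 CPM). With splines of expression, length and GC content their offset was -0.022. Without single libraries the interval held 0 in 2 fits and lay below 0 in 4. The condition written before that fit was run, though after the data were seen (0 held in 4 of 6), was not met. These properties stay an open explanation. The marked class came from the WT list alone, which may lower the offset, so it cannot exclude a rise. Genes listed only for WT, counted as marked, had a median of -0.20 (matched lists -0.02). Those listed only for KO-labelled cells, counted as unmarked, had 0.13 (matched lists -0.01). Loss of a YTHDF2-dependent lowering predicts a fold change that grows with the number of m6A peaks; within the class the slope per doubling of WT peaks was -0.038 (-0.052 to -0.025), and 0.002 (-0.010 to 0.014) for KO-labelled peaks and for peaks in both lists, so no count gave the predicted rise. The fall with WT peaks, though written before that fit as a value against the loss, cannot be read so, because peak listing followed transcript level (median -0.04 in genes with a WT-only peak and 0.16 with a KO-labelled-only peak, against 0.03 and 0.04 in matched lists), and the loss stays open.

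Of the WT m6A peaks, 3784 had no KO-labelled peak, and 37.0% of these overlapped a RIP peak, against 51.1% of shared peaks, which are wider (median 299 against 121 bases). They were 95.4% in the weaker 50% of the WT list by score, as weak peaks near a calling threshold would be, and KO-labelled-only peaks were 99.4% in that of their list. A lower transcript level cannot account for all of them, since 57.2% (55.6 to 58.8) lay in genes with a fold change below 0. It may account for part, since that share was 20.7 percentage points above that of shared peaks (SE over genes 1.06). A loss of methylation stays open and was not tested.

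Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. The real split gave 861 genes and the highest other split gave 1.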
